A study of Mus musculus with 17 samples.

How the data were processed

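Gene expression was measured by RNA sequencing of total RNA (TRIzol and RNeasy, BGI DNBseq, per the labels) from ventricular myocytes of 60-day-old mice. Cells were isolated by Langendorff perfusion with Liberase, plated on laminin for 3 h and treated with actinomycin D at 2 µg/mL. Groups were taken from the labels: KO at 0, 4 and 8 h and WT at 0 and 8 h with 3 libraries each, and WT at 4 h with 2. The labels do not say whether replicates came from separate animals, or whether equal replicate numbers mark the same animal.

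The authors deposited a table of raw counts, in the unit count, for 55487 Ensembl genes, and a table of ratios, in the unit ratio, for 20174 genes. The submitters' processing notes name STAR, featureCounts, DESeq2 and limma and the build names GRCm38 and mm10; their versions and roles are not given in the sources used here. Whether counting used strand and how reads with several positions were treated is also not given. The deposited ratios were compared with the counts. All 297307 nonzero values equalled, within a relative tolerance of 1e-06, the count divided by 1 of 17 factors (0.964 to 1.06), times a constant per library (0.917 to 1.04), divided by the gene's mean over the 3 baseline libraries of its genotype. The factors followed the position of the gene in the table, cycling over libraries from gene to gene. A single factor per library left 0.945% of values within that tolerance, with a median deviation of 1.53%. Genes with no baseline counts in 1 or both genotypes were left out of the ratio table.

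Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (13230 genes holding 99.9% of counts), libraries were scaled by TMM, and 1 quasi-likelihood model of the 6 groups was fitted with robust dispersion, giving a biological coefficient of variation of 5.28%. The quasi-likelihood F tests compared KO with WT at each time, each later time with baseline within genotype, and the difference of these changes (the interaction) at 4 h, at 8 h and jointly. P-values were adjusted by Benjamini-Hochberg over the tested genes within each comparison, with calls at 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Interaction tests at 4 and 8 h share the baseline libraries. CPM values are TMM-scaled. Principal components were computed from log2 CPM with a prior count of 2. Esr1 ratios carry exact Poisson (conditional binomial) 95% intervals, which cover counting error only.

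Before the data were examined, 24 gene lists (pathways, complexes and cell type markers), the rule for named genes and the alternatives were fixed. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over lists within each comparison, beside camera with an estimated correlation and fry. Within each list members were also adjusted over the list alone. Genes were named if they passed an adjusted p of 0.05 and a mean log2 CPM of 3, had no predicted or clone name and, for comparisons of a pair of groups, had no overlap between libraries of the groups. The 10 highest and 10 lowest were taken for baseline KO against WT, WT at 8 h and the 8 h interaction, and the 5 highest and 5 lowest for other comparisons, with the Mbnl genes and the extreme members of each list; 1 gene is not reported here. Ratios were tested with limma (eBayes with trend) on log2(ratio + 0.01).

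Gene symbols, positions and 3′ UTR sequences came from GENCODE M21 on GRCm38, which held 55140 of the 55487 gene identifiers (99.4%). Motif and length relations used 11906 tested genes with an annotated 3′ UTR (90%), and 2-sided permutation tests with 100000 resamples over a family of 6 relations. Libraries of one group were checked for duplicates over 16 pairs. The log2 Pearson r was 0.991 to 0.992. The median squared difference was 1.24 to 1.82 times that of Poisson counting, so none was a copy of another. A spread this near counting error does not show that replicates came from separate animals. Over 40 pairs of equal replicate number, residuals correlated at -0.0469 to 0.0382, so the numbers were not used as pairs.

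The model was tested on simulated counts with 50 genes per fold change. These genes were changed in KO at 8 h only, and no other difference between groups was simulated. The false calls found there therefore do not cover errors of scaling in the real comparisons, where far more genes differ. For a 2-fold interaction at 8 h it called 37 of 50 (74%), 24 of 24 above a mean log2 CPM of 3, with 3 false among 87 calls. For a 2-fold KO against WT difference at 8 h it called 82%. A bound set beforehand on the first share was missed and was replaced, after that result, by recovery above the floor, unbiased folds and few false calls. Alternatives were RLE factors, library size alone, scaling by ribosomal protein counts, no filter on low counts, a CPM of 1 in 3 libraries, DESeq2 1.42.0, a fit of the compared groups only, replicate blocks, and leaving out each library. For the ratios they were a pseudocount of 0.1, the count filter, a block and leaving out each library. Leaving out mitochondrially encoded genes, and multiplying the cycled factors out of the ratios, were chosen after seeing the data. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.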

Results

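RNA was measured in ventricular cardiomyocytes isolated from 60-day-old mice labelled as MBNL1 knockout (KO) or as wild type (WT). MBNL1 is an RNA-binding protein of the muscleblind family that acts on the splicing, localisation and turnover of transcripts. The plated cells were given actinomycin D, which blocks transcription, at 2 µg/mL and were harvested before treatment and after 4 and 8 h. Each genotype and time had 3 libraries, except WT at 4 h with 2, for 17 libraries in all. Library totals ran from 17059736 to 17971617 gene counts, and 13230 genes entered the tests. Mitochondrially encoded genes held 35.1 to 43.3% of each library. All fold changes compare shares of the library after scaling, so a rise during the block is a rise relative to other transcripts. The labels do not say that replicates came from separate animals. P-values therefore measure the spread between these samples, which lay near counting error, and may not cover variation between animals.

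The first principal component of the log2 CPM values held 42.2% of the variance and the second 24.3%. At each time the KO-labelled libraries lay above the WT-labelled ones on both components, and within each genotype the libraries moved along both components from baseline to 8 h. Libraries of one group lay closer to each other than to any other group.

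**Figure D1:**
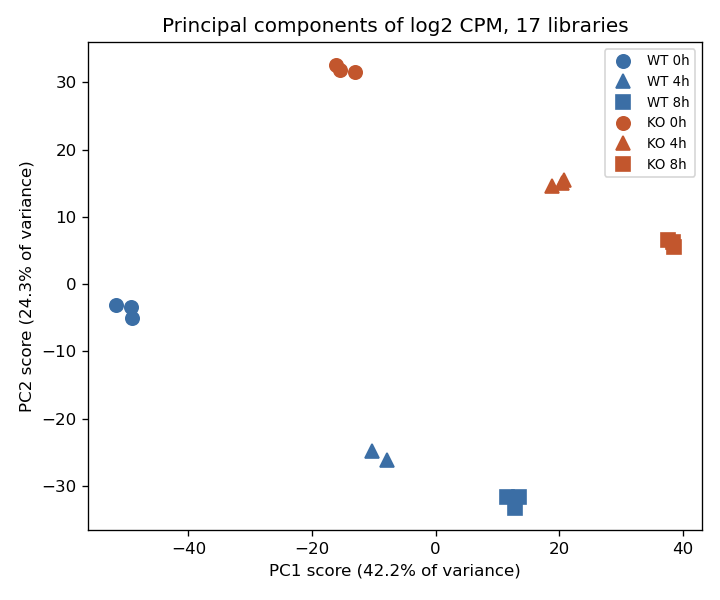
Principal component scores of log2 CPM for the 17 libraries, with component 1 (42.2% of variance) across and component 2 (24.3%) up; colours mark genotype labels and marker shapes mark hours of actinomycin D. Each of the 6 groups forms its own cluster.

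Mbnl1 itself (ENSMUSG00000027763, GRCm38 chromosome 3, 60472830 to 60629750, forward strand) was not lower in the KO-labelled libraries with TMM scaling. Its level was 100 ± 5.36 CPM (SD, n = 3) at baseline in KO against 87.5 ± 1.3 CPM (n = 3) in WT. It was 102 ± 3.14 (n = 3) against 92.1 ± 1.15 CPM (n = 2) at 4 h and 104 ± 3.03 (n = 3) against 86.8 ± 1.23 CPM (n = 3) at 8 h. The baseline log2 fold change was 0.19 ± 0.05 (SE, adjusted p = 8.1e-04) with edgeR, and it changed sign to -0.01 with library size alone and -0.14 with ribosomal protein scaling. At 4 h it was 0.14 ± 0.05 (SE, adjusted p = 0.0329) and was called lower with ribosomal protein scaling, at -0.22 (adjusted p = 0.0127). With TMM scaling replaced by library size alone the 4 h call was lost (adjusted p = 0.29), as it was without KO replicate 3 at 4 h (adjusted p = 0.139) and without WT replicate 2 at 4 h (adjusted p = 0.0727). One count per gene does not show a deletion of part of the gene, and the labels do not say which part was changed, so these values do not check the genotype. The paralogue Mbnl2 had a baseline log2 fold change of 0.11 ± 0.05 (SE, adjusted p = 0.0735) with edgeR, turning to -0.10 with library size alone and to a called -0.22 (adjusted p = 0.00899) with ribosomal protein scaling. Mbnl3 had too few counts to be tested. Genotypes are therefore named as the libraries are labelled.

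The largest difference between the labels was in 1 gene. Esr1, the gene of oestrogen receptor alpha (ENSMUSG00000019768, GRCm38 chromosome 10, 4611593 to 5005614), had 36443 to 46057 counts in each of the 9 KO-labelled libraries and 0 to 57 in each of the 8 WT-labelled ones. Summed over groups and divided by library totals, KO exceeded WT 21096-fold at baseline (6 WT counts; 95% exact Poisson interval 9692 to 57487). The ratio was 39039 at 4 h (10807 to 322364; 2 WT counts) and 1543 at 8 h (1225 to 1972; 72 WT counts, of which 57 lay in replicate 3). These intervals cover counting error only. The KO level held through the block, at 2451 ± 127 CPM at baseline and 2315 ± 49.5 CPM at 8 h (SD, n = 3 each).

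**Figure D2:**
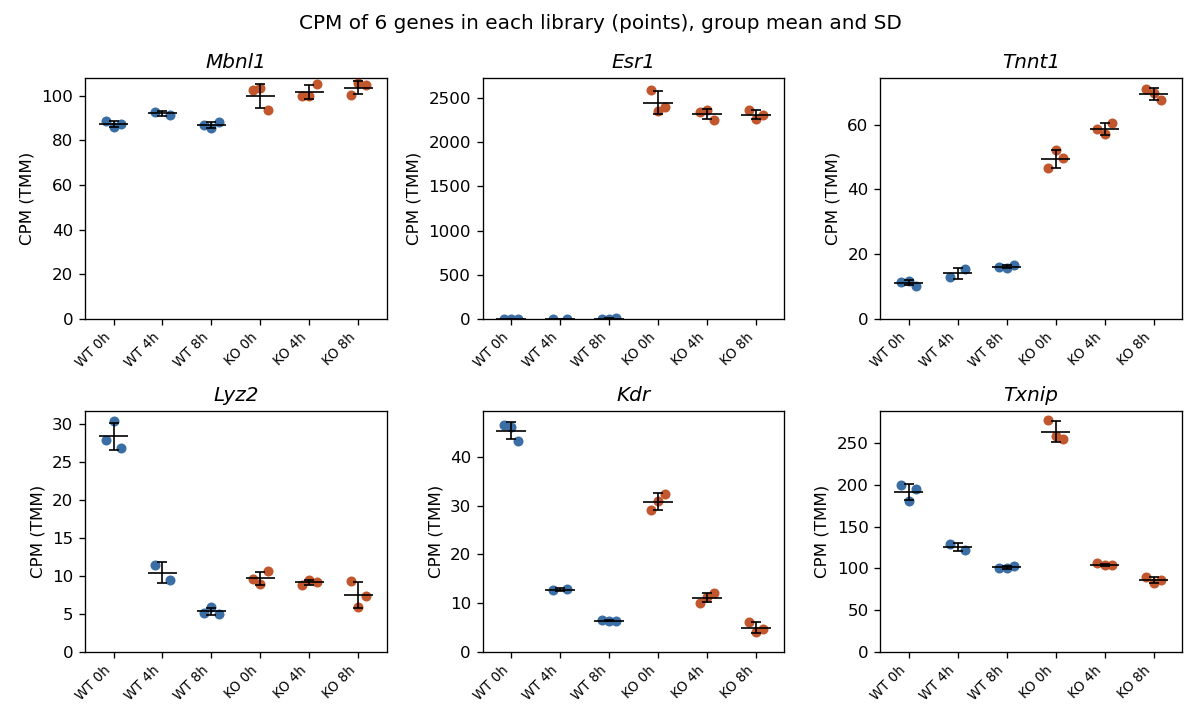
TMM-scaled CPM of Mbnl1, Esr1, Tnnt1, Lyz2, Kdr and Txnip in each library (points), with the group mean (long line) and SD (bars); each panel has its own linear axis from 0. Mbnl1 lay at or above the WT level in KO, Esr1 was near 0 in WT and at 2253 CPM or more in KO, Lyz2 fell from 28.3 to 5.3 CPM in WT, and Kdr and Txnip fell in both genotypes.

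The comparison of untreated cells asked which transcripts differed in steady-state abundance between the genotypes. Besides Esr1, the largest increase in KO among named genes was in Emilin2, an extracellular matrix glycoprotein gene (ENSMUSG00000024053, GRCm38 chromosome 17, 71252172 to 71311978), with a log2 fold change of 2.28 ± 0.07 (SE, adjusted p = 7.3e-36) by edgeR. Tnnt1, the slow skeletal troponin T gene (ENSMUSG00000064179, GRCm38 chromosome 7, 4504570 to 4516382), followed at 2.16 ± 0.07 (SE, adjusted p = 5.3e-36) and stood at 49.5 ± 2.84 CPM in KO and 11.1 ± 0.797 CPM in WT (SD, n = 3 each). The adhesion molecule gene Icam1 (2.09 ± 0.08), the myosin light chain genes Myl1 (1.83 ± 0.08) and Myl9 (1.60 ± 0.11) and the actin-depolymerising factor gene Dstn (1.38 ± 0.05) were also higher. So were the uridine phosphorylase gene Upp1 (1.33 ± 0.11) and the interferon-induced genes Rsad2 (1.33 ± 0.18) and Igtp (1.32 ± 0.07). The largest decreases were in Nr4a1, an immediate early nuclear receptor gene (ENSMUSG00000023034, GRCm38 chromosome 15, 101254269 to 101274795), at -2.45 ± 0.06 (SE, adjusted p = 3.4e-41) by edgeR, Cenpf (-1.95 ± 0.10), a kinetochore protein gene, and Cpxm2 (-1.66 ± 0.07). Lower levels were also found for the epoxide hydrolase gene Ephx1 (-1.59 ± 0.09), the sodium channel subunit gene Scn4b (-1.56 ± 0.06), the lysozyme gene Lyz2 (-1.55 ± 0.09) and the desaturase gene Scd4 (-1.53 ± 0.07). Sox4 (-1.31 ± 0.10), the mitochondrial carrier gene Ucp3 (-1.30 ± 0.07) and the calcium release channel gene Itpr1 (-1.29 ± 0.09) were lower too. Every library of one genotype lay above every library of the other for each of these genes, as the choice of named genes required.

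In all, 4851 of 13230 genes passed an edgeR adjusted p of 0.05 at baseline, 2486 higher and 2365 lower in KO (907 higher and 5564 lower with library size alone, and 471 higher and 7629 lower with ribosomal protein scaling). Those scalings moved the median of all genes by -0.21 and -0.33 log2, so directions of small changes are relative to the scaling.

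Among the gene groups fixed in advance, contractile and energy genes were higher in KO at baseline with TMM scaling. Of the nuclear-encoded oxidative phosphorylation genes, 50 of 54 were higher (51 adjusted over the list alone), with a median log2 fold change of 0.36 (camera adjusted p = 4.6e-20), 0.16 with library size alone and 0.03 with ribosomal protein scaling. Sdhb, a subunit of complex II, was at 0.66 ± 0.04. Of the adult sarcomere genes, 20 of 25 were higher (20 adjusted over the list alone, median 0.33, camera adjusted p = 4.9e-10, 0.12 with library size alone and no higher than 0 with ribosomal protein scaling). Among them the alpha-actinin gene Actn2 was at 0.71 ± 0.04, while the actin-binding repeat gene Xirp2 was lower at -0.31 ± 0.04. Glycolytic genes had 14 of 23 higher (14 adjusted over the list alone, median 0.19, camera adjusted p = 2.6e-05, turning to -0.02 with library size alone and -0.14 with ribosomal protein scaling). Pgam1 led them at 0.81 ± 0.10. Fetal and stress cardiomyocyte genes had 9 of 17 higher and 4 lower (9 and 4 adjusted over the list alone, median 0.20, camera adjusted p = 0.00699, -0.01 with library size alone and -0.13 with ribosomal protein scaling). Vim, the gene of the intermediate filament vimentin, was at -0.45 ± 0.08. Ribosomal protein genes had 63 of 76 higher (67 adjusted over the list alone, median 0.38, camera adjusted p = 6.0e-18, 0.05 with ribosomal protein scaling), although this call was lost with an estimated correlation (adjusted p = 0.139 with an estimated correlation). The same held for fatty acid oxidation (median 0.17, camera adjusted p = 0.0239; adjusted p = 0.0929 with an estimated correlation; -0.04 with library size alone and -0.16 with ribosomal protein scaling). It also held for the mitochondrially encoded genes (median 0.72, camera adjusted p = 0.00142; adjusted p = 0.237 with an estimated correlation). Without KO replicate 3 at baseline their median was 0.38, and the log2 fold change of mt-Atp6 (not called) turned from 1.16 to -0.48. Mitochondrial genes together held 39.5, 43.3 and 40.3% of the KO baseline libraries and 41.8, 38.0 and 36.0% of the WT ones. For mt-Co1 alone these shares were 15.9, 16.8 and 15.3% against 18.4, 17.1 and 16.5%. The shares overlapped between genotypes, so the median does not show a rise in total mitochondrial RNA.

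Immediate early genes were lower in KO at baseline, with 28 of 36 below WT (29 adjusted over the list alone, median -0.60, camera adjusted p = 2.2e-10). Markers of other cell types moved with the genotype labels. Macrophage and leukocyte markers had a median of -1.34 (camera adjusted p = 1.5e-08) with 16 of 17 lower (16 adjusted over the list alone). Fibroblast and matrix markers had a median of -0.88 (camera adjusted p = 9.6e-07) with 15 of 18 lower (15 adjusted over the list alone), such as the actin-severing gene Gsn at -0.87 ± 0.07. Endothelial markers had 11 of 18 lower (11 adjusted over the list alone, median -0.27, camera adjusted p = 0.00831; adjusted p = 0.152 with an estimated correlation). The caveolin gene Cav1 was at -0.89 ± 0.07 and the receptor gene Flt1 at 0.35 ± 0.07 (0.14 and no longer called with library size alone). Of the p53 response genes, 6 of 16 were lower (6 adjusted over the list alone, median -0.20, camera adjusted p = 0.0254; adjusted p = 0.0651 with an estimated correlation). The list test called none of the remaining 12 groups at baseline. Their medians were 0.05 for MBNL and partner splicing factors, -0.04 for mRNA decay factors, 0.03 for calcium handling (mean -0.02), 0.05 for cardiac transcription factors, -0.02 for cell cycle, -0.09 for Hippo targets and 0.08 for heat shock genes (mean -0.08). They were -0.01 for small RNA host transcripts, -0.04 for pericyte, -0.54 for erythroid, -0.85 for atrial and -0.13 for sex-linked transcripts. Among 24 lists, 12 passed camera at a preset correlation of 0.01 and 7 with an estimated one.

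During the block the same comparison at 4 h and at 8 h asked whether the genotype difference persisted. Tnnt1 stayed higher in KO at 2.06 ± 0.08 and 2.11 ± 0.07, Emilin2 at 2.28 ± 0.09 and 2.46 ± 0.08, and Myl9 at 2.06 ± 0.14 and 1.80 ± 0.11 (log2 fold changes at 4 and 8 h; SE). Nr4a1 stayed lower at -2.50 ± 0.07 and -2.27 ± 0.07, Cenpf at -1.92 ± 0.11 and -2.26 ± 0.10, and Ephx1 at -1.90 ± 0.10 and -2.04 ± 0.10. Lyz2, lower in KO at baseline, was at -0.19 ± 0.12 (SE, adjusted p = 0.234) at 4 h and higher at 0.50 ± 0.13 (SE, adjusted p = 0.00205) at 8 h by edgeR. At 4 h 4228 genes passed, 1932 higher and 2296 lower (1432 higher and 2695 lower with library size alone, and 331 higher and 7473 lower with ribosomal protein scaling). At 8 h 3647 passed, 1837 higher and 1810 lower (949 higher and 3046 lower with library size alone, and 1015 higher and 2010 lower with ribosomal protein scaling; 1760 and 1140 with DESeq2). Of the genes tested, 1935 were called at all 3 times, and 1924 of these in the same direction.

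With TMM scaling oxidative phosphorylation genes stayed above WT, with 49 of 54 called higher at 4 h (51 adjusted over the list alone, median 0.39, camera adjusted p = 2.4e-23) and 41 of 54 at 8 h (45 adjusted over the list alone, median 0.27, camera adjusted p = 1.2e-15). With ribosomal protein scaling these medians were 0.03 and 0.21, so the difference at 4 h depends on the scaling. Neither list call held (adjusted p = 0.0502 and 0.0832 with an estimated correlation). Ribosomal protein genes had 67 of 76 higher at 4 h (70 adjusted over the list alone, median 0.41, camera adjusted p = 2.4e-23, 0.05 with ribosomal protein scaling; adjusted p = 0.102 with an estimated correlation). Their median was 0.07 (camera adjusted p = 0.0534) at 8 h, when 15 of 76 were higher (14 adjusted over the list alone). It turned to -0.03 with library size alone and was 0.01 with ribosomal protein scaling. Immediate early genes stayed lower, with medians of -0.43 (camera adjusted p = 2.4e-08) at 4 h and -0.40 (camera adjusted p = 7.5e-11) at 8 h. Markers of macrophages had a median of -0.19 (camera adjusted p = 0.749) at 4 h and 0.44 (camera adjusted p = 0.00614) at 8 h (adjusted p = 0.114 with an estimated correlation). Fibroblast markers had medians of -0.65 (camera adjusted p = 0.00303) at 4 h (adjusted p = 0.0502 with an estimated correlation) and -0.68 (camera adjusted p = 6.0e-05) at 8 h. With an estimated correlation 4 lists held at 8 h. Glycolysis was higher (median 0.21, camera adjusted p = 5.1e-06), with 13 of 23 called higher (14 adjusted over the list alone). Its median was 0.11 with library size alone and 0.16 with ribosomal protein scaling. The p53 response list was lower (median -0.33, camera adjusted p = 0.00284), with 8 of 16 called lower (9 adjusted over the list alone). The immediate early and fibroblast lists were lower too. In this order, the 4 lists had camera adjusted p = 0.0223, 0.0257, 0.00552 and 0.0223 with an estimated correlation.

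In WT-labelled cells the time course measured how the share of each transcript changed during the block. No library was taken at 4 or 8 h without actinomycin D. Decay therefore cannot be told apart from effects of time in culture or from a loss of some cells. Kdr, a receptor gene for vascular endothelial growth factor (ENSMUSG00000062960, GRCm38 chromosome 5, 75932827 to 75978458), went from 45.4 ± 1.79 CPM at baseline to 12.8 ± 0.242 CPM (n = 2) at 4 h and 6.38 ± 0.154 CPM at 8 h (SD, n = 3). Its log2 fold change at 8 h was -2.83 ± 0.09 (SE, adjusted p = 2.7e-37) by edgeR. Podxl (-2.61 ± 0.09), Ly6e (-2.58 ± 0.09), Ptprb (-2.53 ± 0.10), Adgrf5 (-2.45 ± 0.07) and Cav1 (-2.28 ± 0.08) also fell by 8 h. The water channel gene Aqp1 (-2.25 ± 0.07), the chemokine gene Cxcl12 (-2.45 ± 0.08) and the macrophage lysozyme gene Lyz2 (-2.41 ± 0.10) fell too, as did the mitochondrial tRNA gene mt-Ta (-2.53 ± 0.17). At the other end, the mitochondrial ribosomal RNA gene mt-Rnr1 rose by 1.69 ± 0.05 and Lars2 by 1.15 ± 0.09. The ribosomal protein genes Rps21 (1.11 ± 0.13), Rpl31 (1.08 ± 0.07), Rpl26 (1.07 ± 0.06) and Rps29 (1.05 ± 0.13) rose too, with Hmgn5 (1.06 ± 0.09) and the histone gene Hist1h2bc (1.05 ± 0.11). The Esr1 value of 3.70 ± 1.06 rested on 57 counts in replicate 3 at 8 h and was 2.04 without that library. Ribosomal protein, histone and mitochondrial RNA genes have near-identical copies in the genome, and the sources used here do not say how shared reads were counted, so their values are uncertain. At 4 h the largest decreases were in mt-Ta (-2.28 ± 0.19), Socs3 (-2.03 ± 0.08), Gadd45g (-1.96 ± 0.11), Kdr (-1.83 ± 0.09) and Ptprb (-1.79 ± 0.11). The largest increases were in mt-Rnr1 (0.95 ± 0.05), Lars2 (0.80 ± 0.10), Gadd45a (0.54 ± 0.07), Dis3l2 (0.51 ± 0.11) and Cpe (0.50 ± 0.05). The call of Dis3l2 was lost without WT replicate 1 at 4 h (edgeR adjusted p = 0.0519) and with ribosomal protein scaling.

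By 8 h 6860 genes had changed in WT, 3314 up and 3546 down (1275 higher and 5898 lower with library size alone, and 50 higher and 11273 lower with ribosomal protein scaling), of which 61 rose and 1151 fell more than 2-fold. At 4 h 3777 had changed, 2106 up and 1671 down (118 higher and 3186 lower with library size alone, and 44 higher and 3011 lower with ribosomal protein scaling; 1283 and 1671 with no filter on low counts). Ribosomal protein scaling moved the median of all genes by -0.66 log2 at 8 h and library size alone by -0.21. Without WT replicate 1 at 4 h the 4 h count was 2361, and without replicate 2 it was 2350.

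All 18 endothelial markers fell at 4 h and at 8 h in WT, with medians of -1.48 (camera adjusted p = 2.6e-24) and -2.26 (camera adjusted p = 1.1e-16). All 17 macrophage markers fell by 8 h (median -2.40, camera adjusted p = 2.5e-11). So did 15 of 18 fibroblast markers (15 adjusted over the list alone, median -1.04, camera adjusted p = 1.7e-05) and 8 of 9 pericyte markers (8 adjusted over the list alone, median -0.65, camera adjusted p = 0.0102). Immediate early transcripts, known for short half-lives, fell in 32 of 36 cases by 8 h (33 adjusted over the list alone, median -1.14, camera adjusted p = 4.3e-16), including Id2 (-1.98 ± 0.19) and Socs3 (-1.81 ± 0.07). Of the mRNA decay factor genes, 19 of 32 fell (20 adjusted over the list alone, median -0.21, camera adjusted p = 0.00267), Zfp36 most at -1.49 ± 0.07. Relative to these, 54 of 54 oxidative phosphorylation genes rose (median 0.51, camera adjusted p = 3.0e-22, -0.16 with ribosomal protein scaling). So did 22 of 25 adult sarcomere genes (22 adjusted over the list alone, median 0.31, camera adjusted p = 1.1e-09, -0.35 with ribosomal protein scaling), such as Tnnt2 at 0.85 ± 0.05. Of the ribosomal protein genes 75 of 76 rose (median 0.66, camera adjusted p = 2.7e-28, -0.01 with ribosomal protein scaling). Fatty acid oxidation rose in 22 of 31 cases (22 adjusted over the list alone, median 0.37, camera adjusted p = 1.7e-06, -0.29 with ribosomal protein scaling). Glycolysis genes rose in 14 of 23 (15 adjusted over the list alone, median 0.30, camera adjusted p = 4.8e-05, -0.36 with ribosomal protein scaling). The calls of the fatty acid oxidation, glycolysis, pericyte and erythroid lists at 8 h were lost with ribosomal protein scaling. The calls for Hippo target genes (median -0.40, camera adjusted p = 0.0432; adjusted p = 0.0655 with an estimated correlation) and erythroid markers (median -1.93, camera adjusted p = 0.0254; adjusted p = 0.0744 with an estimated correlation) were lost with an estimated correlation.

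In the KO-labelled time course at 8 h Kdr (-2.63 ± 0.10), Ptprb (-2.44 ± 0.11), Podxl (-2.37 ± 0.10), the helix-loop-helix inhibitor gene Id2 (-2.35 ± 0.24) and mt-Ta (-2.24 ± 0.15) fell most. The largest increases were in mt-Rnr1 (1.41 ± 0.05), mt-Rnr2 (1.15 ± 0.05), Lars2 (0.95 ± 0.09), the nuclear noncoding RNA Malat1 (0.94 ± 0.21) and the metallothionein gene Mt2 (0.88 ± 0.10). At 4 h the decreases in mt-Ta (-2.33 ± 0.15), mt-Ty (-1.70 ± 0.08), Fosl2 (-1.60 ± 0.08), mt-Tc (-1.58 ± 0.19) and Ptprb (-1.58 ± 0.10) were largest. Those that rose most were mt-Rnr1 (0.76 ± 0.05), Lars2 (0.72 ± 0.09), Mt2 (0.44 ± 0.10), Copz2 (0.40 ± 0.09) and mt-Rnr2 (0.40 ± 0.05). By 8 h 5898 genes had changed, 2830 up and 3068 down (1495 higher and 3989 lower with library size alone, and 27 higher and 8214 lower with ribosomal protein scaling). By 4 h 3293 had, 1506 up and 1787 down (870 higher and 1814 lower with library size alone, and 19 higher and 4582 lower with ribosomal protein scaling; 1916 and 1438 with no filter on low counts). The calls of Malat1 at 8 h and of Mt2 and Copz2 at 4 h were lost with ribosomal protein scaling.

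All 18 endothelial markers fell by 8 h in KO (median -1.93, camera adjusted p = 3.5e-17). So did 13 of 18 fibroblast markers (13 adjusted over the list alone, median -0.99, camera adjusted p = 9.1e-05) and 7 of 9 pericyte markers (7 adjusted over the list alone, median -1.0, camera adjusted p = 0.00549). Macrophage markers fell in 11 of 17 cases (12 adjusted over the list alone, median -0.65, camera adjusted p = 0.00313; adjusted p = 0.093 with an estimated correlation). Lyz2 was at -0.37 ± 0.11 (SE, adjusted p = 0.00655) by edgeR. Its adjusted p was 0.132 without KO replicate 2 at 8 h and 0.0566 without KO replicate 3 at baseline (range over all alternatives 1.4e-07 to 0.132). Immediate early genes fell in 30 of 36 cases (31 adjusted over the list alone, median -1.01, camera adjusted p = 2.0e-16), while Egr1, a zinc finger transcription factor gene, rose at 0.29 ± 0.05 (-0.10 with ribosomal protein scaling). Oxidative phosphorylation genes rose in 53 of 54 cases (54 adjusted over the list alone, median 0.39, camera adjusted p = 5.1e-21, 0.0048 with ribosomal protein scaling). Ribosomal protein genes rose in 71 of 76 (72 adjusted over the list alone, median 0.37, camera adjusted p = 1.2e-18, -0.02 with ribosomal protein scaling; adjusted p = 0.103 with an estimated correlation). Adult sarcomere genes rose in 19 of 25 (21 adjusted over the list alone, median 0.31, camera adjusted p = 1.4e-07, -0.08 with ribosomal protein scaling), and p53 response genes fell in 7 of 16 (7 adjusted over the list alone, median -0.43, camera adjusted p = 0.0126). At 4 h 18 of 18 endothelial markers (median -1.24, camera adjusted p = 2.7e-21) and 27 of 36 immediate early genes (27 adjusted over the list alone, median -0.89, camera adjusted p = 1.2e-22) had fallen. Macrophage markers had a median of -0.32 (camera adjusted p = 0.16).

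Across the 13230 tested genes, the 8 h log2 fold changes of the KO-labelled and WT-labelled time courses had a Pearson r of 0.784 and a Spearman rho of 0.752; genes are not independent replicates. The slope of KO on WT was 0.707. Of 4653 genes called in both, 4631 moved in the same direction. In both time courses 2370 genes fell, against 822 from independent lists, and 2261 rose, against 709. The time courses share no libraries.

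**Figure D3:**
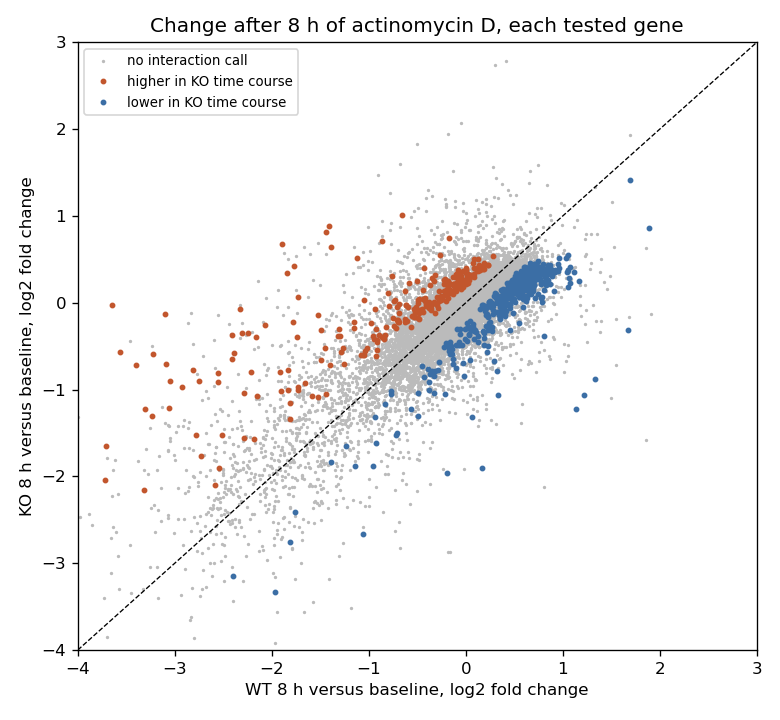
The log2 fold change of each gene from baseline to 8 h in WT (across) and KO (up), for 13200 of 13230 tested genes, with 30 outside the axes; the dashed line marks equal change. Coloured points are genes called in the 8 h interaction, 248 above the line and 440 below it.

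The stated purpose of the series, to find transcripts whose stability depends on MBNL1, corresponds to the interaction, the change over time in KO minus that in WT. Anything else that goes with the labels, as Esr1 does, enters the interaction as well. At 8 h the largest positive value among named genes was in Lyz2 (ENSMUSG00000069516, GRCm38 chromosome 10, 117277331 to 117282321), 2.05 ± 0.16 (SE, adjusted p = 8.3e-15) by edgeR. It fell from 28.3 ± 1.81 to 5.3 ± 0.465 CPM in WT and went from 9.65 ± 0.847 to 7.47 ± 1.7 CPM in KO (SD, n = 3 each). The histocompatibility gene H2-D1 (0.93 ± 0.10), the apolipoprotein gene Apoe (0.92 ± 0.10), the decay factor gene Zfp36 (0.84 ± 0.11), Nme2 (0.82 ± 0.12) and Gadd45g (0.76 ± 0.15) were also positive. So were the sphingosine phosphate receptor gene S1pr1 (0.73 ± 0.14), the invariant chain gene Cd74 (0.72 ± 0.17), Airn (0.68 ± 0.15) and Egr1 (0.64 ± 0.07). Airn overlaps Igf2r on the opposite strand, and the sources used here do not say whether counting used strand, so its value is uncertain.

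Among negative 8 h interactions of named genes, that of the adhesion molecule gene Icam1 (ENSMUSG00000037405, GRCm38 chromosome 9, 21015985 to 21028817) was -0.84 ± 0.13 (SE, adjusted p = 1.5e-05) by edgeR. It went from 8.6 ± 0.502 to 7.43 ± 0.5 CPM in WT and fell from 36.5 ± 4.98 to 17.6 ± 1.14 CPM in KO (SD, n = 3 each). The haem oxygenase gene Hmox1 (-0.79 ± 0.10), Rpl26 (-0.79 ± 0.08), Zfp930 (-0.72 ± 0.18), the mitochondrial nuclease gene Endog (-0.72 ± 0.14) and Txnip (-0.69 ± 0.07), a thioredoxin-binding arrestin gene, were also negative. The calls of Rps21 (-0.75 ± 0.18), mt-Te (-0.79 ± 0.20) and mt-Tp (-0.73 ± 0.18) were each lost without any one of several single libraries (highest edgeR adjusted p = 0.0894, 0.1 and 0.0944). In those fits their values ran -0.79 to -0.64, -0.83 to -0.68 and -0.75 to -0.62. The call of Zfp930 was lost without WT replicate 1 at 8 h (-0.58, adjusted p = 0.0526). In all 688 genes passed, 248 positive and 440 negative (564 higher and 132 lower with library size alone, and 2886 higher and 44 lower with ribosomal protein scaling; 412 and 260 with no filter on low counts). Ribosomal protein scaling moved the median of all genes by 0.28 log2 and library size alone by 0.11. The count was 422 without KO replicate 2 at 8 h, 437 without WT replicate 1 at 8 h and 445 without KO replicate 3 at baseline. Of the positive genes, 187 of 248 fell in WT, and of the negative ones 353 of 440 rose in WT. Among all 13230 tested genes 3546 fell and 3314 rose in WT. The WT change is a term of the interaction, so these shares follow in part from the choice of genes.

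By group, macrophage markers had a median 8 h interaction of 1.75 (camera adjusted p = 8.6e-22), with 12 of 17 called positive (15 adjusted over the list alone). Among them were Mrc1 (1.96), C1qa (1.90) and Csf1r (1.85), given here as list members after their values were seen. The call held with an estimated correlation (adjusted p = 4.3e-04 with an estimated correlation). The mRNA decay factor list was also positive (median 0.16, camera adjusted p = 4.3e-04; 3 of 32 called, 8 adjusted over the list alone), led by Zfp36, whose product destabilises AU-rich transcripts. Ribosomal protein genes had 33 of 76 called negative (43 adjusted over the list alone, median -0.30, camera adjusted p = 9.3e-21; -0.02 with ribosomal protein scaling), a call lost with an estimated correlation (adjusted p = 0.174 with an estimated correlation). Adult sarcomere genes had 10 of 25 called negative (11 adjusted over the list alone, median -0.10, camera adjusted p = 4.3e-04; adjusted p = 0.227 with an estimated correlation), with the median turning to 0.01 with library size alone and 0.17 with ribosomal protein scaling. Among lists called only at the preset correlation was oxidative phosphorylation (-0.09, camera adjusted p = 0.00242; adjusted p = 0.527 with an estimated correlation; 0.01 with library size alone and 0.19 with ribosomal protein scaling). Others were fatty acid oxidation (-0.07, camera adjusted p = 0.0185; adjusted p = 0.129 with an estimated correlation; 0.03 with library size alone and 0.20 with ribosomal protein scaling) and the mitochondrially encoded genes (-0.35, camera adjusted p = 0.00291; adjusted p = 0.333 with an estimated correlation; -0.07 with ribosomal protein scaling and -0.26 without KO replicate 3 at baseline). Endothelial markers (0.22, camera adjusted p = 4.3e-04; adjusted p = 0.111 with an estimated correlation) were another. The last were heat shock genes (-0.10, camera adjusted p = 0.0028; adjusted p = 0.111 with an estimated correlation; 0.17 with ribosomal protein scaling) and MBNL and partner splicing factors (0.10, camera adjusted p = 0.0197; adjusted p = 0.23 with an estimated correlation).

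**Figure D4:**
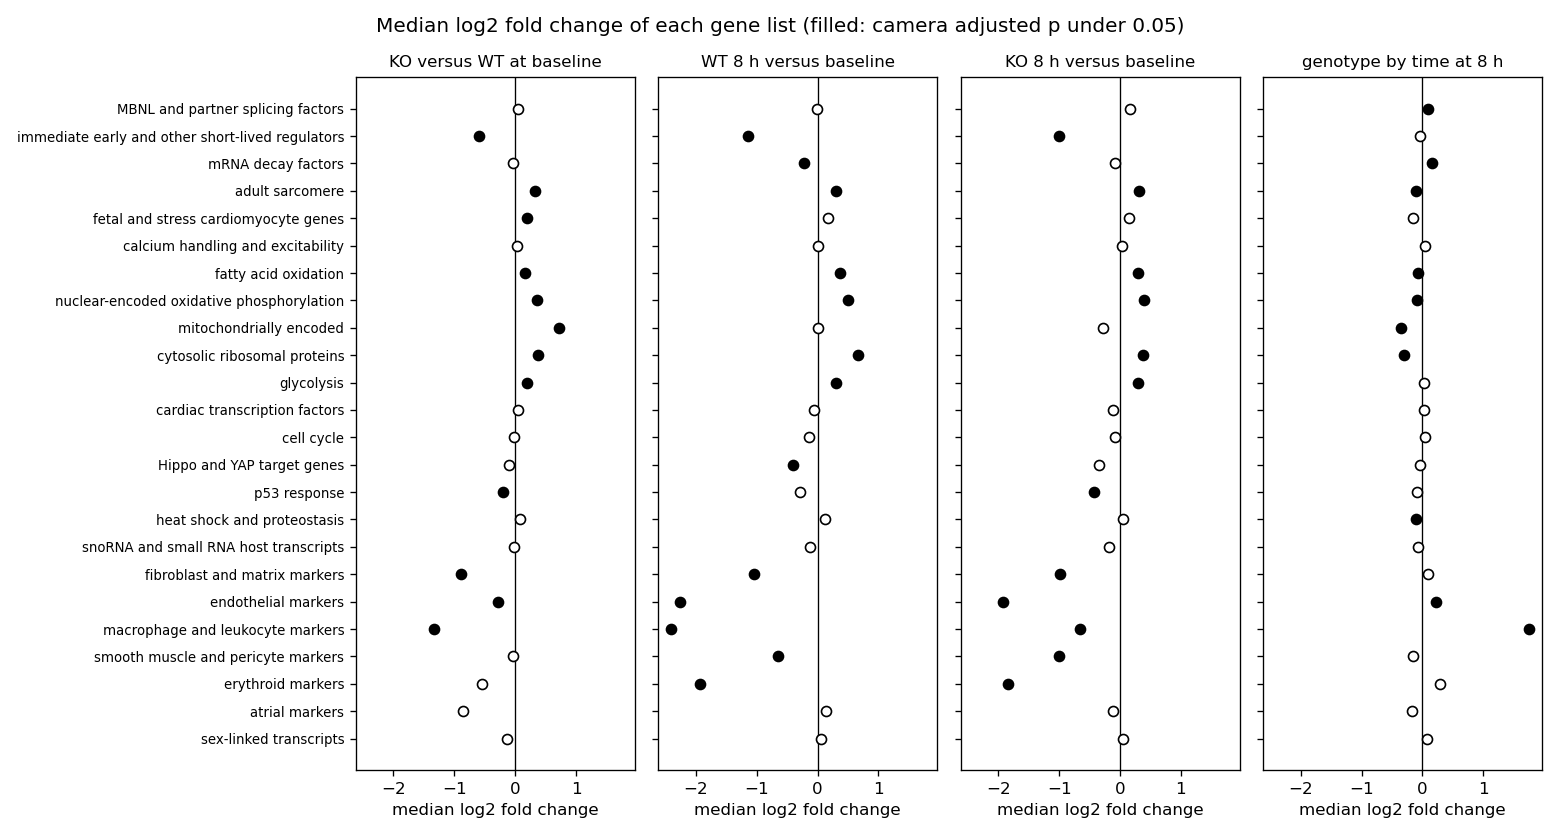
Median log2 fold change of the 24 gene lists fixed in advance, on one axis for 4 comparisons; filled circles passed camera at a preset correlation. Macrophage markers had the largest interaction at 8 h (1.75). With ribosomal protein scaling, medians such as that of adult sarcomere genes in WT at 8 h changed sign (0.31 to -0.35).

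At 4 h the interaction was called for 46 genes, 32 positive and 14 negative (98 and 2 with library size alone, 20 and 8 with ribosomal protein scaling, 16 and 8 with DESeq2, 57 and 10 with no filter on low counts, 48 and 9 when only the compared groups were fitted). Lyz2 led at 1.36 ± 0.15 (SE, adjusted p = 8.2e-09) by edgeR, followed by Gadd45g (0.96 ± 0.16), Apoe (0.83 ± 0.11), H2-D1 (0.78 ± 0.11) and the endothelial adhesion gene Pecam1 (0.62 ± 0.14). Txnip (-0.73 ± 0.07), the cell cycle inhibitor gene Cdkn1a (-0.56 ± 0.12), the growth factor gene Csf1 (-0.53 ± 0.10), Ppp1r10 (-0.52 ± 0.10) and Arrdc3 (-0.46 ± 0.11) were negative. The calls of Pecam1, Cdkn1a, Csf1, Ppp1r10 and Arrdc3 were each lost without WT replicate 1 at 4 h, which leaves 1 library in that group. Their values were then 0.61, -0.50, -0.44, -0.47 and -0.50, and Arrdc3 was at -0.36 without WT replicate 2. The calls of Pecam1, Cdkn1a, Ppp1r10 and Arrdc3 were also lost without single libraries of other groups (highest edgeR adjusted p = 0.155, 0.0827, 0.0664 and 0.191). The whole count was 26 without KO replicate 2 at 4 h and 27 without KO replicate 2 at baseline. Macrophage markers had a median of 0.96 (camera adjusted p = 8.8e-19) with 7 of 17 called positive (12 adjusted over the list alone). Endothelial markers had a median of 0.34 (camera adjusted p = 8.6e-07) with 3 of 18 called (8 adjusted over the list alone), and fibroblast markers one of 0.24 (camera adjusted p = 3.6e-04). These 3 calls held with an estimated correlation. Calcium handling (-0.07, camera adjusted p = 0.0045; 0.08 with library size alone) and cardiac transcription factor lists (-0.08, camera adjusted p = 0.00648; 0.08 with library size alone) passed only at the preset correlation (adjusted p = 0.0872 and 0.143 with an estimated correlation). So did the mitochondrially encoded (-0.49, camera adjusted p = 6.8e-05; -0.40 without KO replicate 3 at baseline) and ribosomal protein (0.04, camera adjusted p = 0.00648) lists (adjusted p = 0.217 and 0.617 with an estimated correlation). A joint edgeR test of both interaction terms called 691 genes (3785 with ribosomal protein scaling, 440 without KO replicate 2 and 452 without WT replicate 1 at 8 h).

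The authors' second deposited table gives each gene's level relative to the baseline mean of its own genotype, so that a KO against WT comparison of ratios addresses the same difference in decline. In it Lyz2 was at 0.661 ± 0.156 of baseline in KO and 0.161 ± 0.015 in WT at 8 h (SD, n = 3 each). Apoe was at 0.969 ± 0.0488 and 0.485 ± 0.0348, and Txnip at 0.279 ± 0.0142 and 0.455 ± 0.0271. With limma on log2(ratio + 0.01), 1360 of 20174 genes differed at 8 h and 27 at 4 h (1109 and 26 with the authors' cycled factors removed). This test takes the baseline means as exact, so it leaves out the spread of the baseline libraries. Among 13223 genes in both tables, 493 of the 688 called from counts at 8 h were also called from the ratios, against 67.2 from independent lists. At 4 h 8 of 46 were, against 0.0626; both tests rest on the same libraries. Without KO replicate 2 at 8 h the 8 h count was 532, without WT replicate 1 615, without KO replicate 1 650, without WT replicate 3 692 and without WT replicate 2 785. The 4 h count was 15 with a pseudocount of 0.1, 16 with a replicate block, 82 with the count filter, 82 without WT replicate 1 and 79 without WT replicate 2 at 4 h.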

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

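The tests of the macrophage and ribosomal protein patterns were chosen only after the result was seen; the splits of the libraries, the motif and length relations, the non-myocyte test and the baseline share were chosen before. The results here are those in which the time course differed between KO and WT by an interaction test.

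By edgeR the change over time differed for 46 genes at 4 h, 688 at 8 h and 691 in the joint test. At 4 h the named genes were Lyz2 (1.36), Gadd45g (0.96), Apoe (0.83), H2-D1 (0.78), Pecam1 (0.62), Txnip (-0.73), Cdkn1a (-0.56), Csf1 (-0.53), Ppp1r10 (-0.52) and Arrdc3 (-0.46), as log2 differences. At 8 h the positive ones were Lyz2 (2.05), H2-D1 (0.93), Apoe (0.92), Zfp36 (0.84), Nme2 (0.82), Gadd45g (0.76), S1pr1 (0.73), Cd74 (0.72), Airn (0.68) and Egr1 (0.64). The negative ones were Icam1 (-0.84), mt-Te (-0.79), Hmox1 (-0.79), Rpl26 (-0.79), Rps21 (-0.75), mt-Tp (-0.73), Zfp930 (-0.72), Endog (-0.72) and Txnip (-0.69).

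Lists that differed by camera at a preset correlation and held with an estimated one had medians of 0.96 (macrophage), 0.34 (endothelial) and 0.24 (fibroblast) at 4 h and 1.75 (macrophage) and 0.16 (mRNA decay) at 8 h. The other calls were lost with an estimated correlation. At 4 h these were 0.040 (ribosomal protein), -0.072 (calcium handling; 0.08 with library size alone), -0.079 (cardiac transcription factor; 0.08 with library size alone) and -0.49 (mitochondrially encoded), with adjusted p = 0.617, 0.0872, 0.143 and 0.217. At 8 h they were 0.22 (endothelial), 0.098 (MBNL and partners), -0.30 (ribosomal protein) and -0.35 (mitochondrially encoded), with adjusted p = 0.111, 0.23, 0.174 and 0.333. So were -0.10 (sarcomere), -0.074 (fatty acid oxidation), -0.092 (oxidative phosphorylation) and -0.10 (heat shock), with adjusted p = 0.227, 0.129, 0.527 and 0.111. With ribosomal protein scaling these 4 turned to 0.17, 0.20, 0.19 and 0.17.

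Splits of the libraries do not decide whether chance can be excluded for the count at 8 h. In them 13 of 100 gave at least the real 688 genes by edgeR, and the highest other gave 5765. That highest split exchanged the genotypes whole at one time, and the others that gave as many kept the genotypes whole at 8 h (6 of 8) or at baseline (5 of 10), which puts the genotype difference into the contrast. The 80 that mixed genotypes at both times put it into the spread within groups, so their low counts say nothing either. Across the 688 genes, the baseline difference made up a median share of 0.827 of the interaction (quartiles 0.422 to 1.22). That difference is a term of the interaction and the genes were chosen for it, so the share does not decide whether chance values in the baseline libraries made it. The WT and KO libraries also differed at baseline, in 4851 genes by edgeR. Whether a difference in starting level, and not in decline, gave rise to the interaction of a gene was not tested. YGCY motifs, to which MBNL proteins bind, did not relate to the 8 h interaction across genes (Spearman rho 0.00527, permutation p = 0.567, Benjamini-Hochberg adjusted 0.68). This argues against their density as a main cause of its spread over all genes with an annotated 3′ UTR. An effect on a small set of genes is not excluded, since 688 of 13230 tested genes were called.

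Macrophage markers had a median change of -2.40 in WT and -0.65 in KO by 8 h. The list's KO against WT median moved by 1.77 between baseline and 8 h, which restates the interaction and so does not test a fixed difference in macrophage RNA. For a higher share of all non-myocyte RNA in the WT baseline, 3 of 3 other non-myocyte lists had 8 h interaction medians more than 0.5 away. This does not decide, since such a share need not give every list the same interaction. Baseline medians of these and the macrophage list ran from -1.34 (macrophage) to -0.04 (pericyte). At 4 h the endothelial (0.34) and fibroblast (0.24) interaction medians were positive too, while camera did not call the pericyte list. A single deviating library is argued against by a lowest median of 1.67 without any 1 library. The genotype, with anything else that goes with the labels, also stays open. So does a change in the macrophages present at isolation, at a Lyz2 level of 28.3 ± 1.81 CPM in WT and 9.65 ± 0.847 CPM in KO (SD, n = 3 each). Neither was tested.

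Ribosomal protein transcripts had a median 8 h interaction of -0.30. Transcript length and level are argued against as the whole cause, since 0% of 10000 gene sets matched on both had as low a median (lowest -0.179). The middle of those sets was -0.0795, against a median of -0.0166 over all tested genes, so length and level may account for part. Drawn sets do not carry the correlation between ribosomal protein genes, so their spread may be too narrow. RLE factors, library size alone and leaving out mitochondrial genes left a median of -0.195 or lower, which argues against those scalings, while scaling on these genes themselves brings it near 0 by construction (-0.02). The list call was lost (adjusted p = 0.174 with an estimated correlation). Reads shared with pseudogene copies stay open, as does the genotype with anything else that goes with the labels.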

How the results depend on the processing

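Leaving out mitochondrially encoded genes and removing the cycled factors from the ratios were tests chosen only after the result was seen; the others were fixed before. Of 6063 values of named genes under alternatives, 5806 kept their direction and side of the threshold, 131 lost the call, 61 gained it and 65 reversed. Of 384 list values, 307 kept both, 75 lost the call and 2 reversed. Ribosomal protein scaling gave 8100 genes for KO against WT at baseline, 7804 at 4 h, 11323 for WT at 8 h, 28 and 2930 for the interaction at 4 and 8 h and 3785 in the joint test. The 4 h interaction gave 100 genes with library size alone and 24 with DESeq2. The cause was not tested. Under every other alternative except those leaving out a library, the counts of genes from the count table stayed within 1.5 times those reported. Lists called with an estimated correlation numbered 7 at baseline, 1 at 4 h and 4 at 8 h for KO against WT, 7 for WT at 4 h, 7 for KO at 4 h, and 3 and 2 for the interaction at 4 and 8 h. Fry, which does not compare a list with other genes, called 21 for KO at 8 h and 15 for KO against WT at 4 h, and ribosomal protein scaling 6 for the 8 h interaction. With that scaling the fatty acid oxidation and oxidative phosphorylation lists turned from down to up at 8 h in the interaction (adjusted p = 0.646 each).

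Without each library in turn, counts ran 4167 to 4930 (baseline), 2963 to 4279 (4 h) and 2983 to 3719 (8 h) for KO against WT. They ran 2350 to 3840 and 6208 to 6993 for WT and 2600 to 3376 and 5247 to 5959 for KO at 4 and 8 h. For the interaction they ran 26 to 53 at 4 h, 422 to 830 at 8 h and 440 to 827 jointly (440 without KO replicate 2 and 452 without WT replicate 1 at 8 h). For the ratios they ran 21 to 82 at 4 h and 532 to 1560 at 8 h. Where WT at 4 h kept 1 library, that library was assumed to vary like the other groups. With the cycled factors removed the ratio counts were 1109 at 8 h and 26 at 4 h. The 4 h ratio count was 15 with a pseudocount of 0.1, 82 with the count filter, which leaves fewer genes tested, and 16 with a replicate block. Blocks gave 880 and 63 genes for the interaction at 8 and 4 h. Low counts limit the interaction: in simulated data a 1.5-fold one was called for 18 of 50 genes.

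With DESeq2 in place of the reported choice, log2 values of opposite sign were found for KO vs WT 0 h, Cox7a1 0.018 and for WT 8 h, Mbnl1 0.017 and for KO vs WT 4 h, Mbnl2 0.0021. With RLE factors in place of the reported choice, log2 values of opposite sign were found for KO vs WT 0 h, Cox7a1 0.018 and for WT 8 h, Mbnl1 0.016 and for KO vs WT 4 h, Mbnl2 0.0021. With library size alone in place of the reported choice, log2 values of opposite sign were found for WT 8 h, Abcc9 -0.086, Fbln1 -0.079, Mbnl2 -0.13, Nr4a3 -0.048 and for KO 8 h, Mbnl1 -0.054 and for KO vs WT 0 h, Mbnl1 -0.013, Mbnl2 -0.098 and for WT 4 h, Mbnl1 -0.10 and for interaction 4 h, Mbnl1 0.10, Mbnl2 0.020 and for interaction 8 h, Rbm20 0.078. With mitochondrially encoded genes left out, they were found for KO vs WT 4 h, Mbnl2 0.0040. With no filter in place of the reported choice, log2 values of opposite sign were found for interaction 4 h, Mbnl1 0.023 and for KO vs WT 4 h, Mbnl2 0.013 and for interaction 8 h, Rbm20 0.028. With only the groups compared, they were found for interaction 4 h, Mbnl1 0.015 and for KO vs WT 4 h, Mbnl2 0.0034. With ribosomal protein scaling in place of the reported choice, log2 values of opposite sign were found for WT 8 h, Abcc9 -0.53, Acaa2 -0.0016, Ankrd1 -0.035, Dis3 -0.33, Etfa -0.028, Fbln1 -0.53, Mbnl2 -0.58, Ndufa9 -0.41, Nr4a3 -0.50, Rps27a -0.35 and for KO 8 h, Ccng1 -0.060, Egr1 -0.099, Fbln1 -0.11, Mbnl1 -0.34, Mbnl2 -0.16, Rpl3 -0.22, Sdhd -0.18 and for interaction 8 h, Dis3 0.11, Rbm20 0.25 and for KO 4 h, Mbnl1 -0.20, Mbnl2 -0.11 and for KO vs WT 4 h, Mbnl1 -0.22 and for KO vs WT 0 h, Mbnl1 -0.14, Mbnl2 -0.22 and for WT 4 h, Mbnl1 -0.11. Without 1 library at a time, values that crossed 0 ran Cox7a1 -0.069 to 0.042 (KO vs WT 0 h), Mbnl1 -0.019 to 0.051 (KO 4 h), Mbnl2 -0.044 to 0.047 (KO vs WT 4 h), Rbm20 -0.079 to 0.011 (interaction 8 h), Ttn -0.19 to 5.8e-04 (WT 8 h), mt-Atp6 -0.48 to 1.64 (KO vs WT 0 h), mt-Atp6 -1.43 to 0.69 (interaction 8 h), mt-Co3 -1.11 to 0.15 (KO vs WT 0 h). The cause was not tested.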

Other observations

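Only the tests on Esr1 in this part were chosen after the result was seen. Single members of lists differed between genotypes, and camera called neither the heat shock nor the Hippo target list at baseline (medians 0.08 and -0.09). The inducible chaperone gene Hspa1b was lower in KO by edgeR, at -0.94 ± 0.09 (SE; adjusted p = 2.9e-13) at baseline and -1.43 ± 0.13 (SE; adjusted p = 7.6e-14) at 8 h, and it fell over 8 h in WT (-1.20 ± 0.09) and KO (-1.69 ± 0.13). Hspa5, the chaperone gene of the endoplasmic reticulum, was lower at -0.46 ± 0.04 and -0.53 ± 0.04, while the mitochondrial chaperonin gene Hspe1 was higher at 0.54 ± 0.06 and 0.36 ± 0.06. Among Hippo pathway targets Ccn2 was higher at baseline (0.73 ± 0.06) and Ptpn14 lower (-1.13 ± 0.09), with 4 of 17 tested members higher and 4 lower (the same numbers adjusted over the list alone). The natriuretic peptide gene Nppa was higher at baseline (0.69 ± 0.05) and 8 h (0.80 ± 0.05), and the sodium-calcium exchanger gene Slc8a1 at 0.47 ± 0.04 and 0.62 ± 0.04.

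Among cardiac transcription factor genes, a list that camera did not call at baseline, Hand2 was higher in KO at that time (0.56 ± 0.08) and Prox1 lower (-0.77 ± 0.06), with 6 of 25 tested members higher and 4 lower (6 and 4 adjusted over the list alone). Over 8 h in WT 11 of 25 fell (11 adjusted over the list alone; median -0.06, camera adjusted p = 0.182), among them Foxo3 (-0.61 ± 0.06). The splicing factor gene Rbm24 was higher in KO at baseline (0.30 ± 0.05). The nuclear noncoding RNA Neat1 was lower in KO at baseline (-0.97 ± 0.10) and fell in WT by 8 h (-0.60 ± 0.10).

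The Esr1 transcript in KO-labelled libraries was weighed against 3 explanations. By library total, without TMM scaling, the lowest KO-labelled level was 627 times the highest WT-labelled one. This argues against an exchange of single libraries between the genotypes, which would break that separation. The separation would remain if all labels of the genotypes were exchanged. Such an exchange stays open, although it would not account for the transcript itself. Activity of the whole neighbourhood is argued against, since 11 tested genes within 2 Mb had a median baseline log2 fold change of 0.063 (-0.78 to 0.34). Transcripts of an introduced construct that holds Esr1 sequence, as inducible Cre fusions do, may be the source, but 1 count per gene does not show which part was read, and the log2 change over 8 h in KO (-0.082) does not decide. The labels used here name no such construct, and if there is one, its effects and those of the knockout cannot be told apart in KO against WT.

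Other values, chosen after they were seen, followed the labels. A1cf had 29 to 38 counts in each KO-labelled library and 0 to 1 in each WT-labelled one, AC117816.1 had 8 to 22 against 0 in every WT-labelled library, and Gt(ROSA)26Sor had 149 to 190 against 23 to 44. A count of 0 allows up to 3 counts per library. Xist had 0 to 3 counts in all 17 libraries. The mitochondrial gene mt-Atp8 had 4436 counts in KO replicate 3 at baseline and 18 to 184 in the others.

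Features of the 3′ UTR were related to the WT change over 8 h across 11906 genes, which are not independent replicates. Longer 3′ UTRs went with larger decreases (Spearman rho -0.25; permutation p = 1e-05, the smallest that 100000 resamples can give; Benjamini-Hochberg adjusted 2e-05), so length may account for part of the spread. AU-rich pentamers per kilobase had a rho of -0.0472 (permutation p = 1e-05, the smallest possible, and 2e-05 adjusted). For the KO change over 8 h the rho was -0.0487 (permutation p = 1e-05 and 2e-05 adjusted). By the bound set beforehand the WT value counts against them as the cause of the spread. It lies near that bound, and the KO value has the same sign, so the test does not decide. For the baseline difference, 2 of 4 non-myocyte lists had medians beyond 0.3 on 1 side (-1.34 for macrophage and -0.88 for fibroblast markers, against -0.27 for endothelial and -0.04 for pericyte markers). A different share of other cells in the preparations therefore stays open as a contribution to it.

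For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. By edgeR the real splits gave 4851 genes for KO against WT at baseline and 3647 at 8 h, 6860 for WT at 8 h, and 3293 and 5898 for KO at 4 and 8 h. The highest other split gave 0 in each, with up to 878, 842, 889, 742 and 773 genes at an unadjusted p under 0.05. Those other splits mix the groups compared, which puts the difference between them into the spread within groups. Their low counts therefore say nothing about chance. No other tool was run on the splits.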
